A study of Mus musculus with 9 samples.

How the data were processed

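RNA sequencing was done on LSK cells, the lineage-negative, Sca1-positive and cKit-positive fraction of mouse bone marrow that holds the blood stem and progenitor cells. Per the labels, cells came from 9 mice aged 6 to 8 weeks on a mixed B6/129 background, given doxycycline at 2 mg/ml with sucrose at 10 mg/ml in the drinking water. Groups were taken from the sample titles: 3 rtTA control mice, 3 K9M mice and 3 K36M mice, each replicate a separate mouse per the series design text. The antibodies used to remove lineage-positive cells were against Mac1, Gr1, B220, CD3e and Ter119, per the labels' protocols.

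The authors deposited a table of RPKM values, which scale reads to transcript length and to library size, for 37882 genes and 9 libraries. Per the submitters' processing notes, CASAVA 1.7, STAR and the mm10 build were used. The STAR version and the counting rule for reads that match several places are not given in the sources used here, so values of genes with near-identical copies are uncertain. The labels name both polyA RNA and a total RNA kit. Of the genes, 12058 were at 0 in every library and no pair of libraries held identical values. Identifiers were matched to GENCODE M21, which uses the same build: 37607 matched by identifier and 135 by a unique symbol. All coordinates are from that annotation on mm10.

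RPKM hides depth, but the lowest values moved in steps that fit single reads. From these steps the libraries held between about 15900000 and 50420000 reads, a ratio of 3.172. With M21 gene lengths, between 57.0% and 61.8% of values worth up to 20 reads came out whole within a tolerance of 0.02, against 4.0% by chance. The reads recovered this way were therefore approximate and served only as an alternative. For a gene of 1 kb, 1 read was worth 0.0198 RPKM in the deepest library and 0.0629 RPKM in the shallowest.

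Values were analysed as log2(RPKM + 0.5) for the 12926 genes with RPKM of at least 1 in at least 3 libraries. Fold changes are on that scale, which understates changes of low genes. limma 3.58.1 in R 4.3.3 fitted the 3 group means to all 9 libraries with eBayes and a mean-variance trend. There were 6 residual degrees of freedom and 3.14 prior degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 24 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. Of 571 list entries, 19 were not matched. Lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Where a list called by camera is given without a fry value, its fry adjusted p was above 0.05. Counts adjusted over the list alone are given beside those over all genes.

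Named genes were H3f3a, H3f3b, Col1a1, Ly6a and Kit, and in each comparison the 5 largest rises and 5 largest falls among called genes whose groups did not overlap. Symbols that are only model or clone numbers were counted and not named by this rule. Missing places were filled by the smallest p and are said not to pass. For a described list, up to 4 called members are named, or 2 uncalled members with the smallest p. Copies of the H3.3 genes were found with blastn 2.17.0 from the coding sequences of H3f3a and H3f3b, each 411 bases, at an identity of at least 90% over at least 300 bases.

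The fit was tested on simulated data for 12926 genes. For K9M against rtTA it recovered 57 of 100 genes changed 2-fold and 84 of 100 changed 4-fold, with 6 unchanged genes called. For K36M against rtTA the numbers were 58, 91 and 8, and for K36M against K9M they were 64, 91 and 11. Noise in the simulated data was drawn independently for each gene and library. Correlation between genes and replicate pairing were left out, so these numbers cannot show how often unchanged genes are called in the real libraries. Replicate numbers shared between groups were checked for pairing by the correlation of deviations from group means across genes, with pairing taken where every same-number pair of the groups compared lay above 0.1. For K36M and rtTA all 3 same-number pairs did, at 0.414, 0.369 and 0.377, against -0.377 to 0.0129 for other pairs, so a value with the replicate number as a block, fitted to all 9 libraries, is given beside a K36M against rtTA result where it changes the call or moves a count by over 1.5 times. This pairing comes from the data, not from the labels. Deviations cancel within a group, so positive same-number values tend to make the other values negative, and the contrast is partly built in. The block fit also includes the K9M libraries, whose numbers did not pair with rtTA or K36M by this rule. Alternatives set in advance were other pseudocounts, filters, scalings, priors, library weights, a block by replicate number, fits to only the groups compared, a 2-fold minimum and leaving out each library. Alternatives chosen after seeing the data were rescaling to protein-coding reads, limma voom on the recovered reads and leaving out pseudogenes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for joins and plots.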

Results

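Gene expression was measured in LSK cells, the bone marrow fraction that holds blood stem and progenitor cells, from mice carrying a doxycycline-controlled histone transgene. K9M mice carried H3.3 with lysine 9 replaced by methionine, and K36M mice carried H3.3 with lysine 36 replaced by methionine, both placed at Col1a1. Control mice carried only rtTA, the doxycycline-dependent activator. No group carried an unmutated H3.3 transgene. Against rtTA, an effect of the mutation therefore cannot be told apart from an effect of carrying an H3.3 transgene. There were 3 mice and 3 libraries per group. Library depth, read from the lowest RPKM steps, was about 16610000, 33860000 and 25020000 reads in rtTA 1 to 3, 48980000, 28280000 and 15900000 in K9M 1 to 3, and 40370000, 36960000 and 50420000 in K36M 1 to 3. Correlation of log2 values across genes had a median of 0.968 within groups and 0.952 between groups. The ranges overlapped, from 0.942 to 0.970 within groups and from 0.932 to 0.969 between groups. On the first principal component, 25.4% of the variance, rtTA 1 lay at -26.7, nearer K9M 1 to 3 (-24.9, -17.8 and -22.3) than rtTA 2 and 3 (5.79 and 10.6). Control library 1 had the largest share of small RNA reads, 3.40% against 1.18% to 2.91% elsewhere.

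The H3.3 genes were examined first, since they check the labels. H3f3a (ENSMUSG00000060743, chromosome 1, 180800832 to 180813943) stood at 224 ± 32.3 RPKM (SD, n = 3) in rtTA, 300 ± 17.5 RPKM in K9M and 460 ± 44.2 RPKM in K36M. It rose in K36M against rtTA by 1.04 on the log2 scale (SE 0.14, limma adjusted p = 0.0141) and did not pass in K9M (0.43, SE 0.14, limma adjusted p = 0.509). H3f3b, which encodes the same protein, stood at 236 ± 33.1, 212 ± 12.8 and 204 ± 22.8 RPKM and was not called in any comparison. H3f3c, annotated as a processed copy of H3f3a on chromosome 2 (119665626 to 119666036, identity 99.0%), rose in both mutants. Its RPKM was 256 ± 52.9 in rtTA, 863 ± 53.002 in K9M (1.77, limma adjusted p = 0.0126) and 2004 ± 374 in K36M (2.97, limma adjusted p = 0.000437). Of 10 tested processed copies of H3f3a, 6 were called higher in K36M and 1 in K9M. Reads of H3f3a and these copies may be exchanged in alignment, so the level of each is uncertain. Exchange among them alone would not raise them all, and in K36M all 10 tested copies had a positive fold change beside H3f3a. In K9M the tested copies also all had positive fold changes, from 0.06 to 2.59. The median of the copies was 1.19 in K9M and 2.61 in K36M. Reads of the H3.3 transgene may also be counted there, and its sequence was not used here. A rise of H3f3a or its copies therefore cannot be told apart from transgene reads. The H3f3a call in K36M ended without K36M replicate 1 (limma adjusted p = 0.0742), without K36M replicate 3 (0.0703), without rtTA replicate 3 (0.0566) and with only the 2 groups compared (0.0799), over a range of adjusted p from 0.00255 to 0.0799 for all alternatives. The H3f3c call in K36M held in each alternative, and in K9M it ended without K9M replicates 1, 2 or 3 or rtTA replicate 2, with no filter and with quantile normalization, with limma adjusted p up to 0.0813.

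**Figure D1:**
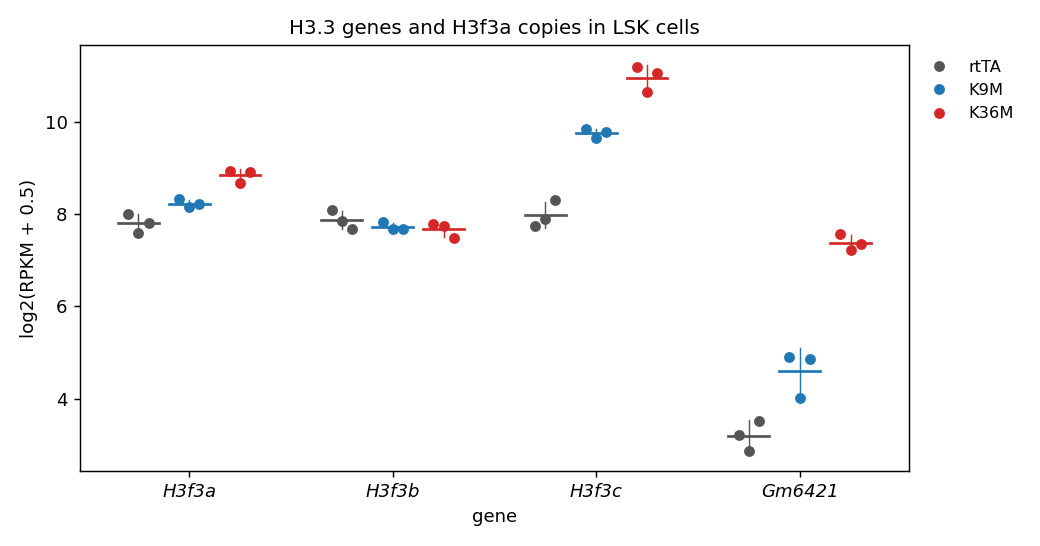
Expression as log2(RPKM + 0.5) of H3f3a, H3f3b, H3f3c and the H3f3a copy Gm6421, the last chosen after its values were seen; points are the 3 libraries of each group, horizontal lines group means and vertical lines ± 1 SD on this scale. Mean H3f3c lies at 7.98 in rtTA, 9.75 in K9M and 10.95 in K36M, while mean H3f3b lies between 7.67 and 7.87.

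The sort markers and the target locus were not called in any comparison. Kit, the cKit receptor of the sort, stood at 95.4 ± 7.17 RPKM (SD, n = 3) in rtTA, 86.4 ± 5.45 in K9M and 66.2 ± 11.3 in K36M (K36M against rtTA -0.54, limma adjusted p = 0.0918). Ly6a, which encodes Sca1, stood at 179 ± 98.0, 152 ± 24.7 and 155 ± 36.4 RPKM. Col1a1 stood at 0.128, 0.111 and 0.317 RPKM, below the filter, and was not tested.

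K9M against rtTA asked what differed in these cells in mice carrying the lysine 9 mutant transgene. Of 12926 tested genes, 15 were called, 12 higher and 3 lower, and 919 had an unadjusted p under 0.05. Afp, the fetal serum protein gene, rose from 2.49 ± 0.41 to 10.2 ± 1.51 RPKM (SD, n = 3; 1.84 on the log2 scale, SE 0.189, limma adjusted p = 0.0103). Akr1c12, an aldo-keto reductase gene, rose from 2.70 ± 0.273 to 11.99 ± 4.63 RPKM (1.91, limma adjusted p = 0.0367). Btg2, an antiproliferative gene and p53 target, fell from 92.9 ± 6.85 to 45.0 ± 2.18 RPKM (-1.04, limma adjusted p = 0.0249). Igha, the IgA heavy chain gene, fell from 30.8 ± 25.6 to 0.079 ± 0.0903 RPKM (-5.41, limma adjusted p = 0.0436).

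Processed pseudogenes made up 8 of these 15 calls, against 8.01% of tested genes (two-sided Fisher's exact p = 6.36e-06); in the other comparisons they made up 10 of 194 and 16 of 326 calls. Rpl3-ps1, a copy of Rpl3 on chromosome X (13202571 to 13203780), was listed at 0 in all rtTA and K36M libraries and stood at 113, 390 and 100 RPKM in K9M replicates 1 to 3 (limma adjusted p = 0.000121, and 0.283 with limma voom on recovered reads). Eif5al3-ps, a copy of Eif5a, rose from 2.81 ± 1.55 to 41.4 ± 2.32 RPKM (SD, n = 3; 3.80, limma adjusted p = 0.00397) and was also called in K36M. Levels of such copies are uncertain because their reads may belong to near-identical sequences. The filling genes Zfp36 (-0.997, limma adjusted p = 0.0524), Rgs2 (-0.97, 0.0821) and Cd79a (-2.001, 0.0821) did not pass.

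The calls of Afp, Eif5al3-ps and Rpl3-ps1 held without each single library. Of the 7 named calls, 4 were lost without K9M replicate 2 or rtTA replicate 2, 3 without K9M replicate 1, K9M replicate 3 or rtTA replicate 3, and 1 without each K36M replicate, with limma adjusted p up to 0.193 for Igha. The count of 15 became 36 without rtTA replicate 1, 8 without rtTA replicate 2, 6 without K9M replicate 2 and 9 without K36M replicate 3. It became 1, Afp, with pseudogenes left out, 4 with no filter, 8 with quantile normalization, 9 with rescaling to protein-coding reads and 62 with library weights. Of 14 other settings, Akr1c12 and Igha each lost the call in 9 and Btg2 in 3. These settings included no filter and pseudogenes left out for all 3 genes. Afp lost its call with no filter (limma adjusted p = 0.0536). Groups did not overlap for 12.5% of tested genes, where chance gives 10%.

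Among the gene lists in K9M, immediate early and heat shock genes, which respond within minutes to stimulation and stress, had negative fold changes for 20 of 20 tested members with a median of -0.86. By limma 0 members were called over all genes, 15 had an unadjusted p under 0.05 and 15 were lower adjusted over the list alone. Camera gave adjusted p = 2.51e-23, adjusted p = 0.108 with an estimated correlation and fry adjusted p = 0.0477. Zfp36 stood at 325 ± 20.1 RPKM (SD, n = 3) in rtTA and 162 ± 7.06 in K9M, and Junb at 189 ± 14.7 and 103 ± 9.28, neither called. In the B lineage list, 0 of 11 members were called by limma, 8 had an unadjusted p under 0.05, 7 were lower adjusted over the list alone, and the median was -1.09. Its camera adjusted p was 1.02e-09, with adjusted p = 0.108 with an estimated correlation and fry adjusted p = 0.0477. Cd79a, part of the B cell receptor, and Pou2af1, a B cell coactivator (-1.60, limma adjusted p = 0.155), did not pass.

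Granulocyte genes in K9M had a median of -1.44 with 0 of 20 called by limma, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 5.74e-06, adjusted p = 0.568 with an estimated correlation and fry adjusted p = 0.605). Camp (-1.67) and Ly6g (-1.93), which belong to mature neutrophils, did not pass. Control replicate 3 held more mature granulocyte RNA than the other controls, with S100a8, chosen after its values were seen, at 2364 RPKM against 546 and 279. Monocyte, macrophage and dendritic genes had a median of -0.68, 0 of 19 called by limma, 1 lower adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 2.61e-05, adjusted p = 0.491 with an estimated correlation and fry adjusted p = 0.526). The mean log2 level of this list was 2.85, 2.88 and 4.04 in rtTA replicates 1 to 3 and 2.67, 2.70 and 2.80 in K9M replicates 1 to 3. Most of the fall in its mean thus rests on rtTA replicate 3. Klf4 (-0.88) and Itgam (-1.15) did not pass. The p53 target list had 1 of 20 members called lower, Btg2, 1 adjusted over the list alone and a median of -0.22 (camera adjusted p = 0.000204, adjusted p = 0.108 with an estimated correlation and fry adjusted p = 0.0477).

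Interferon response genes in K9M had a median of -0.25, 0 of 32 called by limma, 1 higher adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.00016, and adjusted p = 0.651 with an estimated correlation). Xaf1 (0.97) and Usp18 (-0.59) did not pass. Cell cycle genes had a median of 0.12, 0 of 32 called by limma, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0096, and adjusted p = 0.72 with an estimated correlation), with Tyms at 0.42 and Mcm5 at 0.35. Ribosomal protein genes had a median of 0.25, 0 of 39 called by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.000285, and adjusted p = 0.72 with an estimated correlation), with Rpl18 at 0.34 and Rpl15 at 0.35. Median fold changes of the lists not called by camera were -0.02 for long-term HSC, 0.06 for lymphoid priming, -0.05 for T and NK lineage, 0.10 for erythroid, -0.10 for megakaryocyte and 0.03 for mast cell, basophil and eosinophil genes. They were 0.02 for stroma and endothelium, -0.17 for CDK inhibitors, 0.47 for germline genes, -0.05 for imprinted genes, -0.17 for Hox clusters and -0.22 for sex linked genes. For the machinery of H3K9 methylation, H3K36 methylation and Polycomb they were -0.02, 0.01 and -0.05. The clustered protocadherins had 1 tested member (0.12), too few for camera. Of 205 tested entries in these 16 lists, 0 were called by limma and 22 had an unadjusted p under 0.05, and adjusted over the list alone 3 T and NK lineage genes passed, 2 higher and 1 lower. Control replicate 1 bore on the number of lists called by camera, 8 with it and 5 without.

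K36M against rtTA asked the same of the lysine 36 mutant. Of 12926 tested genes, 194 were called, 74 higher and 120 lower, and 2464 had an unadjusted p under 0.05. Immediate early genes were among the falls. Fos fell from 454 ± 16.7 to 163 ± 45.0 RPKM (SD, n = 3; -1.51 on the log2 scale, SE 0.204, limma adjusted p = 0.0164), Nr4a1 from 64.6 ± 19.9 to 14.2 ± 5.07 (-2.16, limma adjusted p = 0.0177) and Fosb from 38.8 ± 13.1 to 5.40 ± 4.15 (-2.90, limma adjusted p = 0.0267). Ptgds, a prostaglandin D synthase gene, rose from 1.05 ± 0.449 to 9.07 ± 0.651 RPKM (2.66, limma adjusted p = 0.00163). Hbb-bt, an adult beta globin gene, rose from 12.2 ± 2.30 to 163 ± 54.7 RPKM (3.64, limma adjusted p = 0.0267).

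Largest rises in K36M also included Eif5al3-ps (4.03), H3f3c (2.97) and the H3f3a copy H3f3a-ps1 (2.37, limma adjusted p = 0.0113), whose levels are uncertain for the reason given above. Largest falls included the granule protein gene Ltf, from 114 ± 137 to 4.02 ± 1.81 RPKM (SD, n = 3; -4.01, limma adjusted p = 0.037), Chi3l3 (-3.66, 0.0341) and an immunoglobulin kappa variable segment, ENSMUSG00000093861 (-3.11, 0.043, and 0.0596 with the replicate block). Trbj1-1, a T cell receptor segment, stood at 3.45 ± 0.92 RPKM in rtTA and was listed at 0 in K36M (limma adjusted p = 0.0259). Its call was lost without each rtTA replicate and without K36M replicates 1 or 3 (limma adjusted p up to 0.115). RPKM scales reads to length, so a given value rests on fewer reads in a short gene segment, and read numbers of this segment are not given here. The Ltf control mean rests on rtTA replicate 3, at 272 RPKM against 42.6 and 27.8. The Ltf call held without that library and was lost without rtTA replicate 1, each K36M replicate or each K9M replicate.

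Calls in K36M that held without each single library were those of Eif5al3-ps, H3f3c and Ptgds, 3 of 27 named. Lost were 24 without K36M replicate 1, 5 without K36M replicate 2, 18 without K36M replicate 3, 13, 16 and 19 without rtTA replicates 1, 2 and 3, and 11, 10 and 12 without K9M replicates 1, 2 and 3, with limma adjusted p up to 0.172 for Hoxa10. The count of 194 became 10, 402 and 23 without K36M replicates 1, 2 and 3, 90, 51 and 26 without rtTA replicates 1, 2 and 3, and 73, 106 and 83 without K9M replicates 1, 2 and 3. Settings gave 25 genes with only the 2 groups compared, 76 with no filter, 98 with at least a 2-fold change and 301 with the replicate block. Of the 27 named calls, 20 were lost with only the 2 groups compared and 14 with no filter. Groups did not overlap for 22.3% of tested genes, where chance gives 10%.

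In the immediate early and heat shock list, 11 of 20 members fell in K36M, 17 were lower adjusted over the list alone, and the median was -1.09. Camera gave adjusted p = 2.35e-18, adjusted p = 0.343 with an estimated correlation and fry adjusted p = 0.0124. Zfp36 fell by 1.25 (limma adjusted p = 0.00918) and Junb by 1.11 (limma adjusted p = 0.0164) on the log2 scale. The Zfp36 call was lost without K36M replicate 1 (limma adjusted p = 0.0551), and the calls of Fos, Nr4a1 and Junb were lost without K36M replicate 1, rtTA replicate 2 or rtTA replicate 3, and that of Junb also without K36M replicate 3. The Fosb call was lost without K36M replicates 1 or 3, K9M replicate 3 or each rtTA replicate, with limma adjusted p up to 0.122. All 5 of these calls were lost with only the 2 groups compared. Beside this list, the mean log2 level of the granulocyte list was 7.06 in rtTA replicate 3 and between 4.35 and 5.45 in the other 8 libraries.

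**Figure D2:**
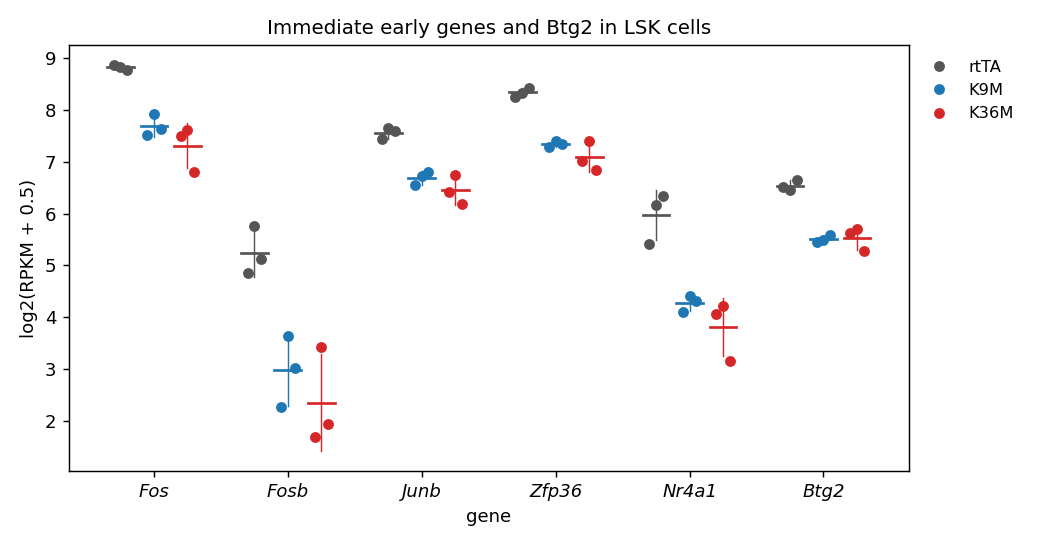
Expression as log2(RPKM + 0.5) of Fos, Fosb, Junb, Zfp36, Nr4a1 and the p53 target Btg2; points are the 3 libraries of each group, horizontal lines group means and vertical lines ± 1 SD on this scale. Mean Fos lies at 8.83 in rtTA, 7.70 in K9M and 7.31 in K36M; of these genes, only Btg2 was called in K9M.

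Cell cycle genes in K36M had positive fold changes for 32 of 32 members, median 0.37, with 0 called by limma over all genes, 22 at an unadjusted p under 0.05 and 13 higher adjusted over the list alone. Camera gave adjusted p = 1.37e-11, adjusted p = 0.487 with an estimated correlation and fry adjusted p = 0.0732. Plk1, a mitotic kinase (0.62, limma adjusted p = 0.0602), and Ccne2, a cyclin (0.70, 0.0637), did not pass. The granulocyte list held 1 rise, the chaperone Calr (0.82, limma adjusted p = 0.0398, lost without each library but K36M replicate 2), and 1 fall, Ltf, with 4 higher and 8 lower adjusted over the list alone and a median of -1.51 (camera adjusted p = 0.185, and adjusted p = 0.831 with an estimated correlation). Its mean log2 level was 5.45, 5.11 and 7.06 in rtTA replicates 1 to 3 and 5.40, 4.35 and 5.22 in K36M replicates 1 to 3. Most of the fall in its mean thus rests on rtTA replicate 3. In its 10 mature granule genes, chosen afterwards, the mean level was 5.48, 4.69 and 7.91 in rtTA replicates 1 to 3. In K36M replicates 1 to 3 it was 3.99, 2.93 and 3.36, so these genes were lower in K36M without rtTA replicate 3 as well. Erythroid genes had 1 call of 18, Hbb-bt, 1 adjusted over the list alone and a median of 0.30 (camera adjusted p = 0.0305, and adjusted p = 0.76 with an estimated correlation). Other globin genes, chosen after their values were seen, stood at 12.6 ± 5.79 RPKM (Hbb-bs) and 10.5 ± 6.04 RPKM (Hba-a1) in rtTA and 17.5 ± 2.14 and 8.95 ± 1.41 RPKM in K36M.

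Long-term HSC genes in K36M had 1 call of 22, the rise of the imprinted gene Ndn (1.15, limma adjusted p = 0.0478, lost without each of the 9 libraries, up to 0.146), with 1 higher and 5 lower adjusted over the list alone and a median of -0.31 (camera adjusted p = 0.029, and adjusted p = 0.671 with an estimated correlation). Lymphoid priming genes had 1 call of 17 (2 with the replicate block), the fall of Cnn3 from 34.2 ± 2.89 to 12.5 ± 2.10 RPKM (SD, n = 3; -1.43, limma adjusted p = 0.00847, and 0.0551 without K36M replicate 1). In that list 2 genes were lower adjusted over the list alone and the median was -0.27 (camera adjusted p = 0.0191, and adjusted p = 0.487 with an estimated correlation). B lineage genes had 0 of 11 called by limma, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0235, and adjusted p = 0.487 with an estimated correlation), and Pou2af1 (-0.97) and Cd79a (-0.90) did not pass. Among Hox genes, Hoxa10 fell by 1.29 (limma adjusted p = 0.0441, lost without 8 of the 9 libraries, K36M replicate 2 being the exception), 4 of 7 were lower adjusted over the list alone and the median was -0.69 (camera adjusted p = 0.00271, and adjusted p = 0.487 with an estimated correlation).

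Btg2 was the p53 target called in K36M (-1.01, limma adjusted p = 0.0111), 1 of 20 and 1 adjusted over the list alone, with a list median of -0.17 (camera adjusted p = 0.0305, and adjusted p = 0.487 with an estimated correlation). Interferon response genes went both ways: Xaf1 rose (1.05, limma adjusted p = 0.0373) and Gbp2 fell (-0.99, limma adjusted p = 0.02), with 1 higher and 2 lower adjusted over the list alone and a median of -0.18 over 32 genes (camera adjusted p = 0.0305, 0.0621 with the replicate block, and adjusted p = 0.818 with an estimated correlation). Lists not called by camera held further single calls: the T cell factor Tcf7 lower (-1.15), the myeloid genes Klf4 (-0.92) and Cd68 (-1.34) lower, the platelet adhesion gene Selp higher (1.97) and the Polycomb gene Rnf2 lower (-0.52). Of 9 single libraries, leaving out 8 ended the calls of Xaf1, Klf4, Cd68 and Rnf2, 7 that of Tcf7, 4 those of Gbp2 and Selp and 2 that of Btg2. Adjusted over the list alone, 6 T and NK lineage genes passed, 4 monocyte, macrophage and dendritic genes, 4 megakaryocyte genes, 2 imprinted genes, 2 Polycomb genes and 1 mast cell, basophil and eosinophil gene. Medians were -0.39 for T and NK lineage, -0.15 for monocyte, macrophage and dendritic, -0.13 for megakaryocyte, -0.18 for imprinted, 0.05 for Polycomb and 0.00 for mast cell, basophil and eosinophil genes. The mean log2 level of the monocyte, macrophage and dendritic list was 2.85, 2.88 and 4.04 in rtTA replicates 1 to 3. In K36M replicates 1 to 3 it was 3.16, 2.98 and 3.44, so the direction of its mean fold change (-0.06) rests on rtTA replicate 3. Lists with 0 calls by limma over all genes and 0 adjusted over the list alone had medians of -0.14 for stroma and endothelium, 0.03 for CDK inhibitors, -0.55 for germline genes, 0.07 for H3K9 methylation machinery, 0.13 for H3K36 methylation machinery, 0.05 for ribosomal proteins and -0.02 for sex linked genes. The 1 tested protocadherin had a fold change of 0.01 on the log2 scale. Of 107 tested entries in these 8 lists, 11 had an unadjusted p under 0.05.

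K36M against K9M compared the mutants directly. The H3f3a copies H3f3c (1.20, limma adjusted p = 0.0207), H3f3a-ps1 (1.39, 0.0455) and Gm6421 (2.78, 0.00465) were called higher in K36M here. H3f3a was not called (0.61, limma adjusted p = 0.0519). The mutants thus differed in H3.3 reads as well as in the lysine replaced, and the part of this in the other calls was not tested. Of 12926 tested genes, 326 were called, 132 higher and 194 lower in K36M, and 2429 had an unadjusted p under 0.05. Among lymphoid genes, Cnn3 fell from 42.5 ± 7.39 to 12.5 ± 2.10 RPKM (SD, n = 3; -1.73 on the log2 scale, SE 0.157, limma adjusted p = 0.00465) and Dntt, the terminal transferase of early lymphoid cells, from 396 ± 148 to 99.96 ± 4.95 (-1.92, limma adjusted p = 0.0124). Among myeloid genes, Cebpe, a granulocyte transcription factor, rose from 2.60 ± 1.05 to 29.3 ± 11.9 RPKM (3.22, limma adjusted p = 0.0148) and Prtn3, a granule protease, from 88.7 ± 37.3 to 377 ± 180 (2.02, limma adjusted p = 0.0433). K36M replicate 2 lay lowest of the 3 for both Cebpe (15.5 RPKM) and Prtn3 (171 RPKM).

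Other large rises in K36M over K9M were Igha (4.08), the haptoglobin gene Hp (3.35), Hbb-bt (3.10) and Trem3 (2.92). Other large falls were Fcrl1 (-1.97, limma adjusted p = 0.00936), Clec10a (-1.93, 0.0112) and the pseudogenes Rpl3-ps1, listed at 0 in K36M, and Rps3a2 (-3.70, 0.0485), both of uncertain level. Calls of Cnn3, Fcrl1 and Rpl3-ps1 held without each single library, 3 of 22 named. Lost were 17, 3 and 19 without K36M replicates 1, 2 and 3, 15, 15 and 17 without K9M replicates 1, 2 and 3, and 0, 4 and 6 without rtTA replicates 1, 2 and 3, with limma adjusted p up to 0.183 for Rnf2. The count of 326 became 31, 509 and 15 without K36M replicates 1, 2 and 3 and 42, 80 and 39 without K9M replicates 1, 2 and 3. Settings gave 118 genes with no filter, 139 with at least a 2-fold change, 568 with voom on recovered reads and 589 with library weights. Of the 22 named calls, 14 were lost with no filter and 6 with only the 2 groups compared. Groups did not overlap for 27.9% of tested genes, where chance gives 10%.

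**Figure D3:**
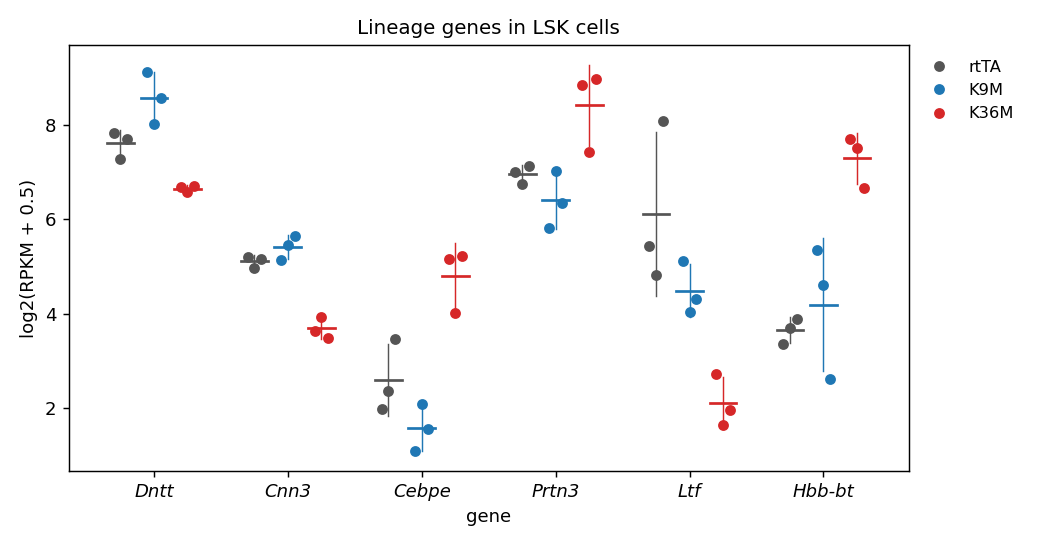
Expression as log2(RPKM + 0.5) of the lymphoid genes Dntt and Cnn3, the granulocyte genes Cebpe, Prtn3 and Ltf and the globin gene Hbb-bt; points are the 3 libraries of each group, horizontal lines group means and vertical lines ± 1 SD on this scale. Mean Dntt lies at 7.60 in rtTA, 8.56 in K9M and 6.65 in K36M, and mean Cebpe at 2.60, 1.58 and 4.80.

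Between the mutants, lymphoid priming genes had 2 falls of 17, Cnn3 and Dntt, 3 lower adjusted over the list alone and a median of -0.24 (camera adjusted p = 0.024, and adjusted p = 0.79 with an estimated correlation). Cell cycle genes had 1 rise of 32, Plk1 (0.67, limma adjusted p = 0.0384), 9 higher adjusted over the list alone and a median of 0.23 (camera adjusted p = 5.54e-06, and adjusted p = 0.79 with an estimated correlation). B lineage genes had 0 of 11 called by limma, 5 at an unadjusted p under 0.05, 0 adjusted over the list alone and a median of 0.62 (camera adjusted p = 0.024, and adjusted p = 0.79 with an estimated correlation), and Cd79a (1.10) and Vpreb1 (1.27) did not pass. Germline genes had 1 fall of 4, the RNA helicase Ddx4 (-1.29, limma adjusted p = 0.0383), 3 lower adjusted over the list alone and a median of -1.02 (camera adjusted p = 0.0229, and adjusted p = 0.739 with an estimated correlation). Long-term HSC genes had 1 fall of 22, Esam (-0.94, limma adjusted p = 0.03), 3 lower adjusted over the list alone and a median of -0.27 (camera adjusted p = 0.0495, and adjusted p = 0.826 with an estimated correlation). Immediate early and heat shock genes had 0 of 20 called by limma, 2 at an unadjusted p under 0.05, 0 adjusted over the list alone and a median of -0.27 (camera adjusted p = 0.024, and adjusted p = 0.826 with an estimated correlation), and Jun (-0.75) and Ier2 (-0.40) did not pass. Of 9 single libraries, leaving out 6 ended the calls of Plk1 and Ddx4, 5 that of Esam and 3 that of Dntt. The number of lists called by camera was 6, and 3 without K9M replicate 2 or 2 without K36M replicate 3. None of the 6 passed fry, whose lowest adjusted p was 0.0943, for germline genes.

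Among lists not called by camera between the mutants, granulocyte genes had 2 rises, Cebpe and Prtn3, and 5 higher and 1 lower adjusted over the list alone, with a median of -0.03 and a mean of 0.13. Monocyte, macrophage and dendritic genes had 2 rises, Cx3cr1 (2.15) and Ly86 (1.95), and 5 higher and 3 lower adjusted over the list alone, with a median of -0.03 and a mean of 0.47. Single calls were Hbb-bt among erythroid genes, Cpa3 lower (-0.92) among mast cell genes, Rnf2 lower (-0.42) among Polycomb genes and Hoxa10 lower (-1.31) among Hox genes. Gbp2 (-0.97) and Ifit2 (-0.75) fell among interferon response genes. Of 9 single libraries, leaving out 8 ended the call of Rnf2, 7 that of Prtn3, 5 those of Cx3cr1, Ly86, Hbb-bt, Cpa3, Hoxa10 and Ifit2 and 4 those of Cebpe and Gbp2. Adjusted over the list alone, 5 T and NK lineage, 2 erythroid, 2 megakaryocyte, 2 mast cell, 3 Polycomb, 2 Hox and 2 interferon genes passed. Medians were -0.34 for T and NK lineage, 0.22 for erythroid, 0.16 for megakaryocyte, 0.38 for mast cell, 0.01 for Polycomb, -0.46 for Hox and 0.00 for interferon genes. Lists with 0 calls by limma over all genes and 0 adjusted over the list alone had medians of -0.21 for stroma and endothelium, 0.21 for CDK inhibitors, -0.01 for p53 targets, -0.17 for imprinted genes, 0.06 for H3K9 methylation machinery, 0.14 for H3K36 methylation machinery, -0.17 for ribosomal proteins and 0.17 for sex linked genes, and the 1 tested protocadherin stood at -0.11. Of 137 tested entries in these 9 lists, 13 had an unadjusted p under 0.05.

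Genes called in both mutants against rtTA numbered 8, with 7 higher and 1 lower and 0 in opposite directions. Higher in both were Eif5al3-ps, H3f3c and Akr1c12, and, chosen after their values were seen, Mrvi1 (1.37 in K9M, 1.84 in K36M), Ccnd1 (0.76 and 0.85), AA465934 (2.48 and 2.21) and Gm8494 (3.12 and 3.31). Btg2 was lower in both. Independent lists would share 0.0687 higher and 0.0279 lower genes. In 100 simulations all 9 libraries were redrawn as unchanged, with independent noise for each gene and 1 control group for both comparisons, and at most 0 genes were shared. Across genes, which are not independent replicates, the correlation of the fold changes was 0.363, against a simulated mean of 0.497, and their covariance was 0.0585, against a simulated mean of 0.0470, a difference of 0.0115. The simulations left out correlation between genes and the pairing of K36M with rtTA. They therefore cannot tell how much overlap, correlation or covariance the shared controls give. Both comparisons use the same 3 controls, which cannot be split into parts of at least 2, so part of the overlap may come from them. Both mutants also carry an H3.3 transgene that the controls lack, and its part in the overlap was not tested. The count of 8 became 19, 2 and 3 without rtTA replicates 1, 2 and 3, 2 without each K9M replicate, 2 without K36M replicate 1 and 5 without K36M replicates 2 or 3. It became 0 with pseudogenes left out, 2 with no filter or with only the 2 groups compared, 4 with quantile normalization or rescaling to protein-coding reads, 5 with median ratio scaling and 28 with library weights.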

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

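Rescaling to protein-coding reads, voom on recovered reads and leaving out pseudogenes were chosen after the data were seen; the others were set in advance. The count of 15 genes for K9M against rtTA became 4 with no filter, 8 with quantile normalization, 62 with library weights, 9 with protein-coding rescaling and 1 with pseudogenes left out, and ran from 6 to 36 without single libraries. The count of 194 for K36M against rtTA became 76 with no filter, 25 with only the 2 groups compared, 301 with the replicate block and 98 with at least a 2-fold change, and ran from 10 to 402 without single libraries. The count of 326 for K36M against K9M became 118 with no filter, 589 with library weights, 595 with the replicate block, 568 with voom and 139 with at least a 2-fold change, and ran from 15 to 509 without single libraries. Lists called numbered 0, 0 and 0 with an estimated correlation, and without single libraries 5 to 10 in K9M, 7 to 10 in K36M and 2 to 7 between the mutants, where no filter gave 3. The 8 genes called in both became 2 with no filter, 5 with median ratio scaling, 4 with quantile normalization, 2 with only the 2 groups compared, 28 with library weights, 4 with protein-coding rescaling and 0 with pseudogenes left out, and ran from 2 to 19 without single libraries. Fewer genes or samples enter by construction where genes or libraries were left out; otherwise the cause was not tested. Of 2152 values of named genes, 12 changed direction, all of uncalled genes. Ly6a turned to 0.17 in K9M and 0.15 in K36M with library weights, and between the mutants to -6.34e-05 with median ratio scaling, -0.020 with library weights and -0.037 with protein-coding rescaling. Without single libraries Ly6a ran from -0.34 to 0.30 in K9M, from -0.33 to 0.31 in K36M and from -0.16 to 0.19 between the mutants, and H3f3b from -0.12 to 0.036 between the mutants. Of 56 calls of named genes, each counted per comparison, 43 were lost in at least 1 alternative set in advance other than leaving out a library, and 47 were lost when 1 library was left out. The replicate block gave 11, 301 and 595 genes, and 7 of 9 libraries correlated best with their own number, a hint from the data and not the design. For K36M against rtTA, where the numbers pair, the block ended 1 named call and 1 list call and changed no other call of a named gene or list there; pairing was judged for each comparison after the block counts had been seen. For K9M against rtTA 1 of 3 same-number pairs lay above 0.1 and for K36M against K9M 0 of 3, so the numbers were not taken as pairs there.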

Other observations

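The splits of libraries and the tests of scaling were set before their results were seen; the other tests here, and the 10 mature granule genes, were chosen afterwards.

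Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. For K9M against rtTA the real split gave 15 genes, the highest other 1, and 1 of 10 splits gave as many. For K36M against rtTA the real split gave 194 genes, the highest other 5, and for K36M against K9M 326 and 6, with 1 of 10 splits as large in each. Replicate numbers pair K36M and rtTA, and the 3 other splits that part all 3 pairs gave at most 0 genes by limma and 12 lists, while the 6 that part 1 pair gave at most 5 genes and 11 lists. Gene lists called by camera numbered 8 in the real split of K9M and rtTA and 11 in the highest other, with 7 of 10 splits as large. For K36M and rtTA these were 9, 12 and 4 of 10, and for K36M and K9M 6, 10 and 5 of 10.

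H3f3a and its processed copies were higher in K36M than in rtTA. Scaling of the libraries is argued against, since the median of the copies stayed at 2.60 after median ratio scaling. A rise of the H3f3a gene alone is also argued against, because the copies rose above H3f3a by 1.40 (SE 0.137). The 10 copies had a median of 2.61, at percentile 100 of 10000 random lists of processed pseudogenes, which restates their rise and decides nothing on its source. Reads of H3.3 transcripts that map to H3f3a and its copies alike therefore cannot be told apart from a rise of the copies themselves, and the transgene sequence was not used here.

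Processed pseudogenes were 8 of the 15 genes called in K9M. A change of the parent gene is argued against by a median ratio of parent to pseudogene fold change of 0.00961, with 8 of 8 ratios under 0.5 and 0 parents called by limma. The segment around Col1a1 is argued against by 0 called pseudogenes within 20 Mb of it. Chromosome segments that differ between mice of the mixed background cannot be told apart from an effect of the mutant, since 1 called pseudogene lay within 2 Mb of another called gene against 0.231 in random draws (permutation p = 0.159). An effect of the mutant histone stays open, as untested.

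The mean level of the immediate early and heat shock list lay below all controls in 6 of 6 mutant libraries, but its camera call was lost in both mutants (adjusted p = 0.108 in K9M and adjusted p = 0.343 in K36M with an estimated correlation), and limma called 11 of 20 members in K36M and 0 in K9M, with 15 there at an unadjusted p under 0.05. A single control library is argued against, since at least 0.967 of the median was kept without any 1 control, and scaling is argued against, since at least 1.02 of it was kept after median ratio scaling. Against fewer granulocytes in the mutant sorts, whose Gr1 and Mac1 antibodies remove such cells, stand medians of -0.90 in K9M and -1.15 in K36M without rtTA replicate 3 against -0.86 and -1.09 with it, and levels of this list of 5.46, 5.81 and 5.64 in rtTA replicates 1 to 3 at mature granule levels of 5.48, 4.69 and 7.91. The 2 mutant libraries that reached the controls in the whole granulocyte list, K36M replicates 1 and 3, lay below them in this list. They decide nothing, since their mature granule levels of 3.99 and 3.36 lay below all controls. Fewer granulocytes still cannot be told apart, since in the 10 mature granule genes 1 mutant library reached the controls and 5 of 6 lay below them. S100a8, the most abundant of these genes, stood at 1063 ± 1135 RPKM (SD, n = 3) in rtTA, 277 ± 150 in K9M and 121 ± 53.1 in K36M. Handling time of the sorts was not tested and stays open beside an effect of the mutants.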
